A study of Mus musculus with 12 samples.

How the data were processed

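The series measured gene expression by RNA sequencing in C2C12 cells, an established mouse myoblast line that divides in growth medium and can fuse into myotubes. Wild-type cells and cells with a knockout of Ddx27, which encodes a nucleolar DEAD-box RNA helicase known for its part in ribosomal RNA processing, were each sampled as total cellular RNA and as RNA from purified polysomes, the mRNAs that carry several ribosomes. Per the labels' protocols, both kinds of RNA were taken up with Trizol and made into standard Illumina libraries. The labels state no selection of poly(A) RNA, no removal of ribosomal RNA, no drug and no clone. They list 12 samples, 3 in each of the 4 groups of genotype and fraction. They do not say whether the 3 of a group came from separate cultures, so no p-value below reaches beyond the spread between samples. Values exist for 11 libraries in the tables analysed here: 3 wild-type total, 3 wild-type polysomal, 2 knockout total and 3 knockout polysomal.

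The authors deposited 1 complete table per genotype, with 13331 genes for the wild type and 13027 for the knockout. The tables share 12590 genes, 741 are listed only for the wild type and 437 only for the knockout, and a gene's highest value was never below 1 in either table. The main columns of the authors' tables hold a signal per gene and library, a normalised read count: every value was a whole number of reads times 1 factor per library, for 100% of values within a tolerance of 0.001 reads. The file names call these values CPM, but the deposited columns summed to between 847338 and 1215073, so the totals are not those of plain CPM, and the scaling was done separately in each genotype's table. Per the submitters' processing notes, STAR, HTSeq, edgeR and the mouse build mm10 were used, with no versions, roles or order stated. The authors' tables also hold a gene length in bases, the authors' log2 fold change of polysomal over total RNA and the authors' FDR, a p-value adjusted for multiple tests. Further deposited tables list the genes past an FDR of 0.05 and a log2 fold change of 1 in size: 1181 higher and 1406 lower in wild-type polysomal RNA, and 410 higher and 526 lower in knockout polysomal RNA, each being exactly the genes past both limits in the complete table. Column names of the knockout table match the sample titles by group but not by number, so knockout libraries carry numbers of their table columns only.

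Reads per library, recovered from the smallest step between values, ran from 13683674 to 27347878. A value of 0 allows up to 3 reads, which is 0.099 to 0.257 normalised read counts depending on the library. These floors, and the 95% intervals given for ratios of reads, cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates differed by far more than counting error: the chi-square per degree of freedom between libraries of a group was 4.03 for wild-type total replicates 1 and 2 (Pearson r of 0.997 across genes) and 21.83 to 592.86 for all other pairs. Gene names came from the tables. Of 13768 gene IDs, 13648 matched the name table of the RefSeq annotation of GRCm38.p6, which is the mm10 build and gave the coordinates. Genes that share reads with near-identical copies, such as Gapdh, the histones and many ribosomal protein genes, have uncertain levels.

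The planned design assumed CPM, and its test was kept, since the normalised read counts differ from CPM by 1 factor per library. Genes with a value of at least 1 in at least 3 of the libraries fitted were tested with limma's linear model with a mean-variance trend (limma 3.58.1 in R 4.3.3) on log2 of the value plus 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adding 1 makes fold changes of low genes smaller than they are. Polysomal RNA was compared with total RNA within each genotype, and the difference between these 2 contrasts was tested with 4 group means over all 11 libraries. Knockout was compared with wild type in total and in polysomal RNA after all 11 libraries were put on 1 scale by the median of ratios. These comparisons and the difference used only genes listed for both genotypes. Levels per group are means of the deposited values with their SD, and fold changes carry their standard error (SE).

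The gene lists were fixed before the data were examined, as were the tests, most of the alternatives and the rule for naming genes. The lists covered cytosolic ribosomal proteins, translation factors, ribosome biogenesis factors, nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, mitochondrially encoded mRNAs, nuclear-retained long non-coding RNAs, small nucleolar RNA host genes, small nucleolar and Cajal body RNAs, replication-dependent histones, myoblast identity, contractile and terminal muscle differentiation, G2/M cell cycle, G1/S DNA replication, extracellular matrix, the integrated stress and unfolded protein responses, p53 targets, the interferon response, the actin cytoskeleton and serum response, and markers of adipocytes, osteoblasts, fibroblasts and leukocytes. Each list with at least 5 tested members was tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the residuals and with fry. A list's call means that it differed from the other genes by camera. The fry test asks instead whether a list's members changed at all. Genes adjusted over the list alone were counted too. The text names Ddx27, then per comparison the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 10 in the higher group and no overlap between the groups' libraries, leaving out model names and pseudogenes. It also takes the 2 members of each list with the smallest adjusted p, up to 2 more where the list was called, genes that stand for a check of the fractions, and Myod1, Myog, Pax7 and Myf5. For the difference between the genotypes, where knockout libraries are not numbered like the samples, no overlap was read from each polysomal library minus the mean total RNA of its genotype. Examples in the text come from these genes.

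The alternatives fixed then were pseudocounts of 0.25 and 4, no filter, a mean of at least 5, the replicate number as a block, median scaling, quantile normalization, no variance trend, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library left out in turn, with the authors' FDR, a log2 limit of 1 in size, all 11 libraries in 1 fit and the other set tests where they apply. A correction for gene length, which removes a smooth trend on log2 length from each library, and a run without the 3 polysomal libraries with over 10% of rRNA-like reads were added after the data were seen. The rRNA-like reads are those of 4 gene models that collect ribosomal RNA sequence (Gm26924, mmu-mir-6236, Lars2 and Gm23935), also chosen after the data were seen. Each test was checked on simulated reads with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 14% and 93% of them for polysomal against total RNA in the wild type, 11% and 92% in the knockout, 2% and 40% for the difference between the genotypes, 18% and 90% for knockout against wild type in total RNA, and 16% and 94% in polysomal RNA. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.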

Results

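Total RNA and RNA from purified polysomes were sequenced from wild-type and Ddx27-knockout C2C12 myoblasts to ask which transcripts are enriched in polysomes and how the loss of Ddx27 changes this. Values were analysed for 3 wild-type total, 3 wild-type polysomal, 2 knockout total and 3 knockout polysomal libraries. The wild-type total RNA replicates 1 to 3 held 18253045, 26347515 and 21518520 reads in the listed genes, and the wild-type polysomal replicates 22986593, 15082167 and 21361037. The knockout total RNA replicates 1 and 2 held 27347878 and 24534451 reads, and the knockout polysomal replicates 1 to 3 held 16471431, 13683674 and 19686754. Levels are normalised read counts, scaled by the authors separately for each genotype, and fold changes are limma's log2 estimates with their standard error.

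Polysomal libraries differed in their share of rRNA-like reads, those of 4 gene models that collect ribosomal RNA sequence. This share was 5.915% (95% Wilson interval 5.905 to 5.924%), 14.547% (14.529 to 14.564%) and 0.674% (0.671 to 0.678%) in wild-type polysomal replicates 1 to 3. In knockout polysomal replicates 1 to 3 it was 23.136% (23.116 to 23.156%), 32.663% (32.639 to 32.688%) and 0.385% (0.382 to 0.387%), and in total RNA it was 0.054 to 0.135%. Libraries also differed in a trend on gene length. Against the mean of their genotype's total RNA, wild-type polysomal replicates 1 to 3 changed by −0.27, −0.63 and −0.16 on the log2 scale per doubling of gene length, so short genes read high in them, and knockout polysomal replicates by −0.19, 0.21 and 0.13. The 2 knockout total libraries differed from each other, at 0.14 and −0.14.

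**Figure D1:**
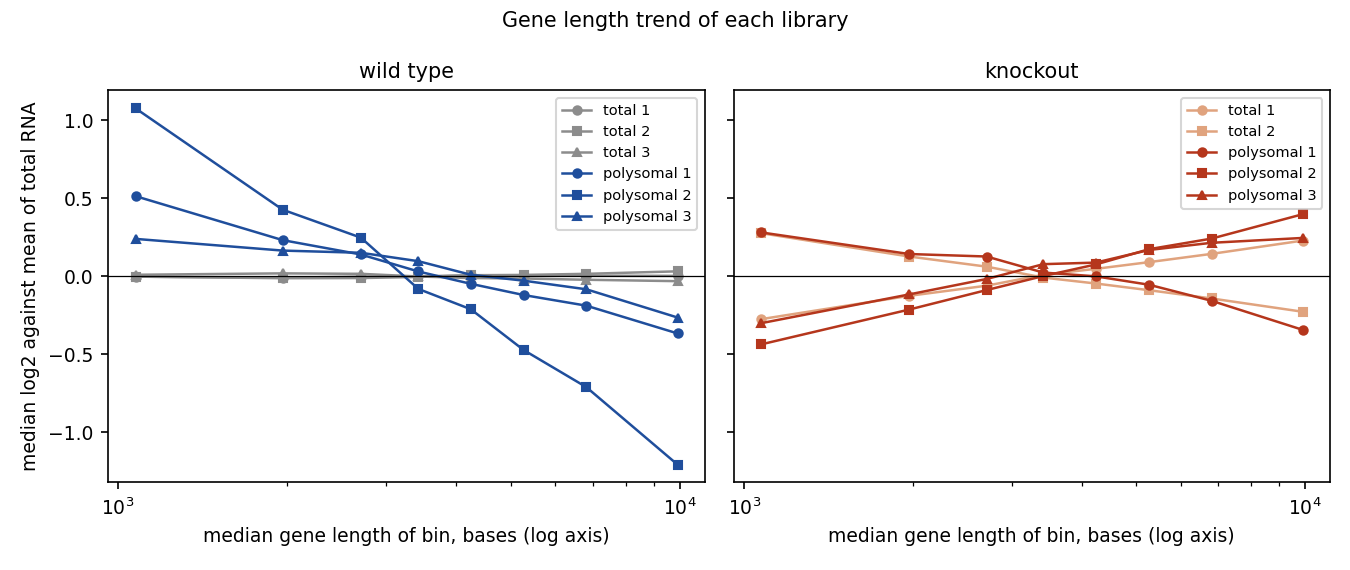
Median log2 level of genes against the mean of their genotype's total RNA (y axis) in 8 bins of gene length in bases (log x axis), 1 line per library. Wild-type polysomal replicate 2, with a slope of −0.63 per doubling, falls with length more than any other library.

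Ddx27 (ENSMUSG00000017999; GRCm38 chromosome 2, 167015313 to 167034945), the targeted gene, was lower in every knockout library than in every wild-type library. Its normalised read counts were 150, 144 and 139 in the wild-type total replicates and 213, 139 and 215 in the polysomal ones, against 39.7 and 45 in the knockout total replicates and 52.6, 41 and 31.3 in the polysomal ones. On 1 common scale Ddx27 fell by 1.62 ± 0.24 (SE; 2 knockout and 3 wild-type libraries, adjusted p = 0.00195) in total RNA and by 2.06 ± 0.22 (3 against 3, adjusted p = 0.000209) in polysomal RNA on the log2 scale, so Ddx27 RNA was reduced and still present. Polysomal over total RNA, Ddx27 stood at 0.36 ± 0.21 in the wild type (adjusted p = 0.243) and −0.05 ± 0.27 in the knockout (adjusted p = 0.932). In the authors' deposited table its log2 fold change was 0.39 (FDR 0.32) in the wild type and −0.03 (FDR 0.975) in the knockout.

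**Figure D2:**
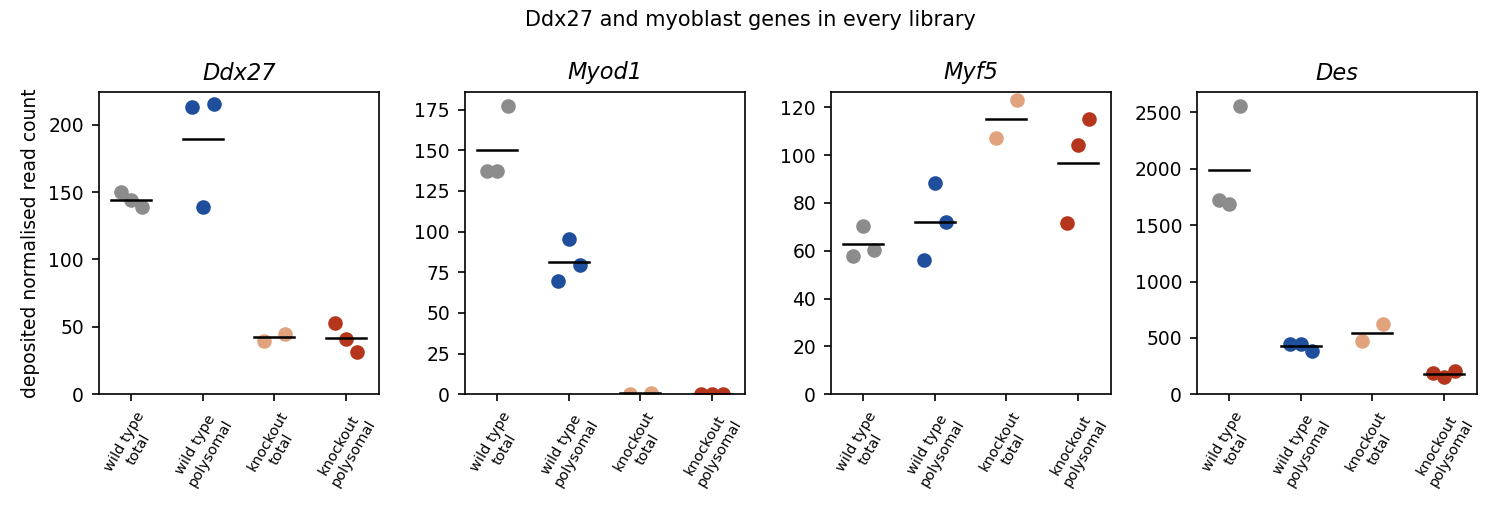
Normalised read counts (y axes, linear) of Ddx27, Myod1, Myf5 and Des per library in the 4 groups, with dots for libraries and bars for group means. Ddx27 lies between 31.3 and 52.6 in the 5 knockout libraries and between 139 and 215 in the 6 wild-type libraries.

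In wild-type myoblasts, transcripts of muscle differentiation were scarce in polysomes compared with total RNA. The embryonic myosin heavy chain Myh3 fell by 4.93 ± 0.40 on the log2 scale (SE, 3 libraries against 3, adjusted p = 0.00115), from 39.0 ± 24.9 normalised read counts (SD, n = 3) in total to 0.181 ± 0.213 in polysomal RNA. The skeletal muscle actin Acta1 fell by 3.95 ± 0.49 (adjusted p = 0.00331), the M-band protein gene Myom2 by 3.74 ± 0.26 (adjusted p = 0.000929) and Myog, the transcription factor of terminal differentiation, by 3.62 ± 0.47 (adjusted p = 0.00368). Of 49 tested contractile and terminal differentiation genes, 44 were lower and 1 was higher, and the same numbers passed when adjusted over the list alone. The list's median was −2.46 (camera adjusted p = 7.45e-22, and adjusted p = 0.178 with an estimated correlation). Mylpf, Mybph, Atp2a1, Tmem8c, Tnnc2 and Chrng, genes of fast muscle contraction, calcium uptake, fusion and the neuromuscular synapse, fell by between 3.32 and 4.12. Its medians in polysomal replicates 1 to 3 were −2.43, −2.36 and −2.51 against mean total RNA.

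The extracellular matrix, fibroblast and myoblast identity lists were lower in wild-type polysomal RNA as well. Fibronectin (Fn1) fell by 2.79 ± 0.19 (adjusted p = 0.000919), from 6230 ± 637 to 899 ± 82.9 (SD, n = 3 each), and the basement membrane and collagen genes Nid2, Col12a1 and Hspg2 stood at −3.26, −3.43 and −2.41. In the extracellular matrix list 33 of 47 genes were lower and 4 higher, 36 and 4 when adjusted over the list alone (median −1.21, camera adjusted p = 3.47e-12, adjusted p = 0.178 with an estimated correlation). All 6 tested fibroblast markers, among them Dcn at −3.20 and Cd248 at −2.01, were lower, as many when adjusted over the list alone (median −1.80, camera adjusted p = 8.78e-05, adjusted p = 0.178 with an estimated correlation). Myoblast identity genes had 17 lower and 4 higher of 31, 18 and 4 when adjusted over the list alone (median −0.96, camera adjusted p = 0.000223, adjusted p = 0.178 with an estimated correlation). Here desmin (Des) fell by 2.20 ± 0.22, Itga7 by 2.01 and Notch3 by 1.97, and Id2, an inhibitor of differentiation factors, rose by 1.80. Myod1, the myoblast determination factor, fell by 0.88 ± 0.20 (adjusted p = 0.02), while Myf5 stood at 0.18 (adjusted p = 0.554) and Pax7 at −0.70 (adjusted p = 0.162). Igfbp5, a secreted growth factor binding protein, fell by 3.55.

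Fos and Fosb, transcription factor genes of the early response to growth signals, were higher in wild-type polysomal RNA. Fos rose by 4.34 ± 0.31 (adjusted p = 0.000988), from 3.87 ± 0.481 to 103 ± 44.3 (SD, n = 3 each), and Fosb by 3.57 ± 0.30 (adjusted p = 0.00115). The actin cytoskeleton and serum response list, which holds Fos, had 10 of 36 genes higher and 11 lower, the latter including Tln1 at −2.55, and did not differ from other genes (median 0.10, camera adjusted p = 0.807). Replication-dependent histone genes were higher for 14 of 18 and lower for 0, 17 and 0 when adjusted over the list alone (median 1.63, camera adjusted p = 1.33e-08, adjusted p = 0.371 with an estimated correlation). The list's medians were 1.43, 2.65 and 1.01 in polysomal replicates 1 to 3, highest in the rRNA-rich replicate 2. The linker histone Hist1h1d rose by 4.49 ± 0.60, Hist1h1a by 3.69, Hist1h1b by 3.66 and Hist1h1e by 3.48, from total RNA levels of 0.266 to 0.571. Among p53 targets 8 of 25 were higher and 0 lower, as many when adjusted over the list alone (median 0.31, camera adjusted p = 0.00957, adjusted p = 0.178 with an estimated correlation). Btg2 stood at 1.85, Psrc1 at 1.74, Mdm2 at 1.05 and Aen at 0.99.

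Of 14 small nucleolar RNA host genes, 9 were higher and 0 lower, as many when adjusted over the list alone (median 1.67, camera adjusted p = 9.92e-06, adjusted p = 0.40 with an estimated correlation). Snhg12 stood at 2.97, Snhg5 at 2.77 and Snhg1 at 2.5, and the list's medians were 1.65, 2.56 and 1.02 in polysomal replicates 1 to 3. Mitochondrial ribosomal proteins had 23 of 73 higher and 0 lower, 38 and 0 when adjusted over the list alone (median 0.75, camera adjusted p = 3.47e-12, adjusted p = 0.194 with an estimated correlation). Mrpl13 stood at 1.42 ± 0.23. Cytosolic ribosomal proteins had 11 of 73 higher and 0 lower, 5 and 0 when adjusted over the list alone (median 0.94, camera adjusted p = 4.97e-11, adjusted p = 0.406 with an estimated correlation). Rpl23 stood at 1.11 and Rpl7 at 1.08, and the list's medians were 0.75, 1.73 and 0.31 in polysomal replicates 1 to 3. Nuclear-encoded oxidative phosphorylation genes had 9 of 75 higher and 2 lower, 5 and 0 when adjusted over the list alone (median 0.65, camera adjusted p = 8.78e-05, adjusted p = 0.406 with an estimated correlation). Cox7b stood at 1.57, and the list's medians were 0.52, 1.18 and 0.13 in polysomal replicates 1 to 3. The medians of the mitochondrial ribosomal, cytosolic ribosomal and oxidative phosphorylation lists, which hold mostly short genes, became 0.44, 0.44 and 0.18 once the length trend was removed, and the oxidative phosphorylation list then did not pass (adjusted p = 0.26), with 2 genes higher and 6 lower. Ribosome biogenesis factors had 21 of 92 higher and 5 lower, 25 and 8 when adjusted over the list alone (median 0.13, camera adjusted p = 0.0248, adjusted p = 0.621 with an estimated correlation). Taf1d stood at 2.74 ± 0.18 and Ebna1bp2 at 1.51, and the list's medians were 0.30, −0.24 and 0.37 in polysomal replicates 1 to 3, so 1 library went the other way. Translation factors had 8 of 47 higher and 3 lower, 11 and 4 when adjusted over the list alone (median 0.24, camera adjusted p = 0.0117, adjusted p = 0.178 with an estimated correlation). Eif4a2 stood at 1.19 and Eif4g1 at −1.26.

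The remaining lists did not differ from other genes in the wild type. Of 43 G1/S replication genes 11 were higher and 2 lower (camera adjusted p = 0.0751), with Gins1 at 1.39. G2/M genes had 3 higher and 4 lower of 40, and the stress response list 5 and 5 of 36, each with camera adjusted p = 0.807. Their medians of −0.04 were 0.01 for both lists under median scaling, and 0 and 0.06 under quantile normalization. Ddit4 and Ppp1r15a of the stress response list rose by 1.67 and 1.42. Mitochondrially encoded mRNAs had 2 of 7 lower, mt-Nd2 at −1.60 and mt-Nd1 at −1.43 (list median −0.589, camera adjusted p = 0.063). After removal of the length trend this list did pass, with a median of −0.975 and 3 lower (camera adjusted p = 0.00524, and adjusted p = 0.343 with an estimated correlation). Interferon genes had 3 of 16 lower (camera adjusted p = 0.162). Nuclear-retained long non-coding RNAs had 2 of 9 higher and 2 lower (camera adjusted p = 0.807), with Xist at −2.68, Pvt1 at 1.86. Malat1, a nuclear-retained RNA, stood at 0.07 ± 0.38 (adjusted p = 0.904), and Neat1, another one, at −1.31 ± 0.39 (adjusted p = 0.049). Both serve as a check of the fractions. Malat1 was not depleted, so RNA from outside polysomes in the polysomal libraries is not excluded. Of markers too few for a set test, 3 of 4 adipocyte and 2 of 4 osteoblast genes were lower. By limma 0 of 2 leukocyte genes and 0 of 3 small nucleolar RNAs were called. Actb at −0.19, Eef1a1 at −0.40 and Gapdh at −0.43 did not pass either (adjusted p = 0.543, 0.198 and 0.492).

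Altogether 1101 genes were higher and 1705 lower of 12380 tested in wild-type polysomal RNA, 560 and 1125 of them by at least 1 on the log2 scale. The lower genes had a median length of 5152 bases and the higher ones 2430, against 3636 for all genes tested. Lars2 and mmu-mir-6236, at 5.41 and 6.94, count among the rises and are gene models that collect rRNA-like reads. Single libraries moved the counts. Every gene still called without a total RNA replicate was also called in the full fit, in the same direction. Without total RNA replicate 1, 2 or 3, 114, 144 or 83 genes were higher and 420, 437 or 378 lower, 594 were higher without polysomal replicate 1, and 2765 were higher and 3012 lower without the rRNA-rich polysomal replicate 2. DESeq2 called 2154 higher and 2215 lower, and the authors' deposited table holds 1735 higher and 1905 lower at its FDR of 0.05.

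**Figure D3:**
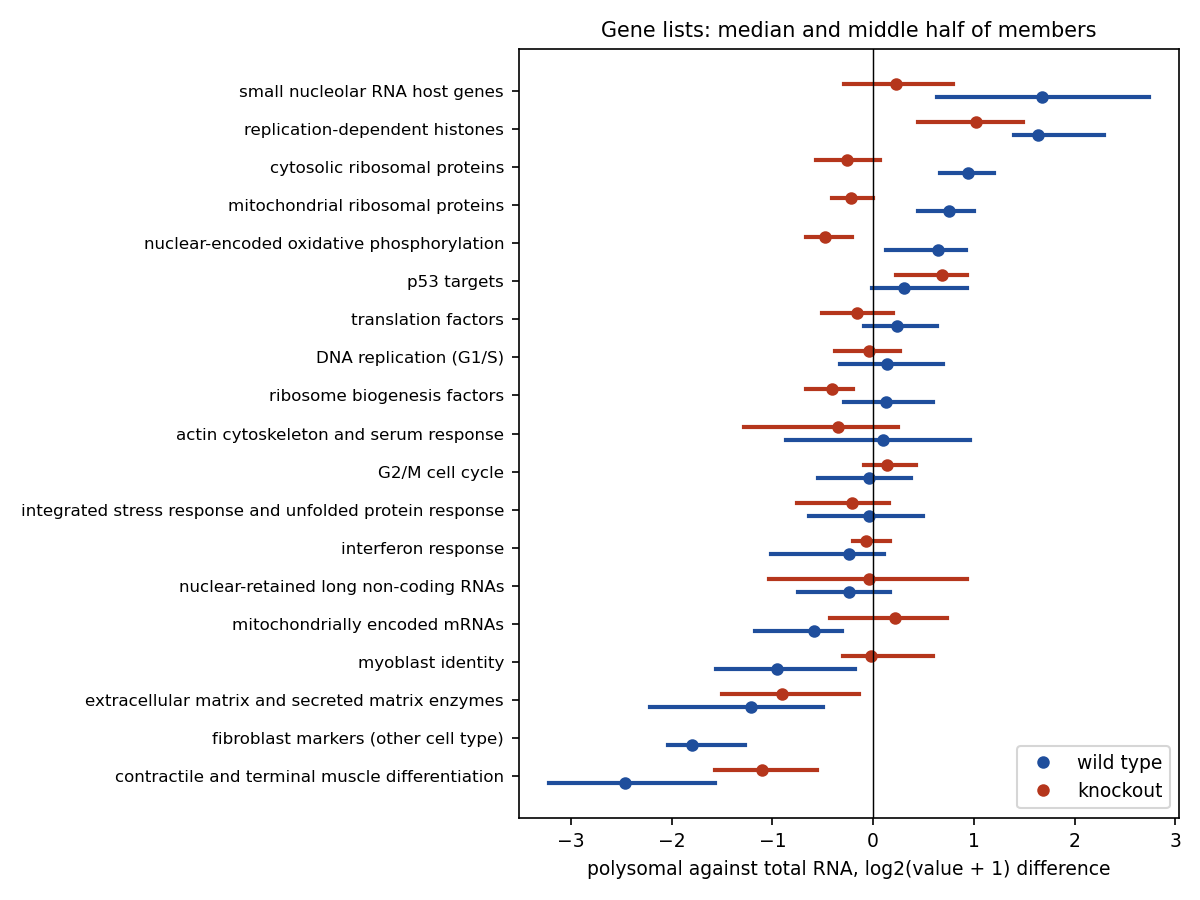
Median log2 fold change of polysomal over total RNA (x axis) for each gene list, with lines for the middle 50% of its members, wild type in blue and knockout in red. Contractile genes have the lowest medians of both genotypes among the lists that passed the set test, at −2.46 in the wild type and −1.10 in the knockout.

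In knockout myoblasts the contractile and extracellular matrix lists were lower in polysomal than in total RNA, and Fos was among the largest rises. Fos rose by 4.64 ± 0.25 on the log2 scale (SE; 3 polysomal and 2 total libraries, adjusted p = 0.000339), from 3.41 ± 0.125 (SD, n = 2) to 110 ± 19.6 (n = 3), and Fosb, Atf3, Dusp1, Klf10 and Btg2 rose by 3.26, 2.90, 2.52, 2.30 and 2.22. Acta1 fell by 3.82 ± 0.27 (adjusted p = 0.00135), Mylpf by 3.31, and Myog stood at −2.41 ± 0.26 (adjusted p = 0.00641). Contractile and differentiation genes had 9 of 35 lower and 0 higher, 25 and 0 when adjusted over the list alone (median −1.10, camera adjusted p = 9.1e-15, adjusted p = 0.318 with an estimated correlation). In the extracellular matrix list 15 of 44 were lower and 0 higher, 28 and 1 when adjusted over the list alone (median −0.91, camera adjusted p = 9.51e-13, adjusted p = 0.368 with an estimated correlation). Nid2 stood at −2.56, Fn1 at −2.31 and Col4a2 at −2.04.

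Other large falls in the knockout were Mgp, a matrix mineralization inhibitor, by 3.69 ± 0.45 (adjusted p = 0.0117), and nestin (Nes), an intermediate filament gene, by 3.12 ± 0.28 (adjusted p = 0.00321). The peptide hormone gene Cck, the aldehyde dehydrogenase Aldh3a1 and the calcium-binding Pvalb stood at −3.46, −3.29 and −3.14. Among p53 targets 3 of 26 were higher and 0 lower, 12 and 0 when adjusted over the list alone (median 0.69, camera adjusted p = 4.87e-06, adjusted p = 0.318 with an estimated correlation). The 3 were Btg2, Ccng1 at 1.44 and Mdm2 at 1.19. Histones had 1 of 21 higher, Hist1h1d at 3.79 ± 0.68, and 8 when adjusted over the list alone (median 1.02, camera adjusted p = 7.22e-06, adjusted p = 0.671 with an estimated correlation). Histone medians were 1.47 and 1.33 in the rRNA-rich polysomal replicates 1 and 2 and 0.22 in replicate 3. In the actin and serum response list 4 of 35 were higher and 7 lower, 6 and 13 when adjusted over the list alone (median −0.35, camera adjusted p = 0.0389, adjusted p = 0.368 with an estimated correlation). Tln1, which links integrins to actin, stood at −2.01.

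Ribosome biogenesis factors had a negative median in the knockout, with 2 of 92 lower, Rrp12 at −1.57 and Tbl3 at −1.32, and 0 higher, 4 and 1 when adjusted over the list alone (median −0.41, camera adjusted p = 6.16e-09, adjusted p = 0.472 with an estimated correlation). Oxidative phosphorylation genes had 1 of 75 lower, Ndufs1 at −1.26, and 0 when adjusted over the list alone (median −0.48, camera adjusted p = 4.87e-06, adjusted p = 0.872 with an estimated correlation). By limma 0 of 73 mitochondrial ribosomal proteins were called (median −0.22, camera adjusted p = 0.0463, adjusted p = 0.909 with an estimated correlation). After removal of the length trend the median was −0.14 and the list did not pass (camera adjusted p = 0.219). Polysomal replicate 1 went the other way, at 0.17 for oxidative phosphorylation and 0.19 for mitochondrial ribosomal proteins, against −0.81 and −0.61, and −0.49 and −0.33, in replicates 2 and 3. Of the cytosolic ones, 1 of 73, Rpl3 at 2.22, was higher (median −0.26, camera adjusted p = 0.0517). Translation factors, with 1 of 47 lower, Eif4g1 at −1.36, did not differ from other genes (camera adjusted p = 0.0993). Neither did the stress response with 2 higher and 2 lower of 35 (camera adjusted p = 0.0886). Myoblast identity had 1 higher and 3 lower of 28, Des at −1.55 and Itga7 at −1.56 among the latter (camera adjusted p = 0.831, with a median that changed sign between scalings).

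The knockout contrast called 110 genes higher and 223 lower of 12070, all of them by at least 1 on the log2 scale, with 2745 at an unadjusted p under 0.05. Leaving out either of the 2 total RNA libraries leaves a group of 1, so how far the counts rest on each of them cannot be told. Without polysomal replicate 1, 2 or 3 it called 862, 35 or 16 higher and 760, 147 or 20 lower. Removing the length trend gave 609 and 855, with 22 contractile, 24 matrix and 20 ribosome biogenesis genes among the lower ones, DESeq2 537 and 751, and the authors' deposited table holds 446 and 630.

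Genes called in both genotypes mostly moved the same way. Among 11805 genes tested in both contrasts, 53 were higher in both (9.8 if independent, Fisher's exact p = 2.56e-27) and 182 lower in both (28.5 if independent, Fisher's exact p = 1.21e-125), while 1 and 3 went in opposite directions (20.1 and 13.9 if independent). Across these genes the fold changes of the genotypes had a Pearson r of 0.44 and a Spearman rho of 0.32. Genes are not independent replicates, so neither Fisher's p-values nor these correlations measure the spread between samples.

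The difference in polysomal enrichment between the genotypes was weak, with a higher polysomal over total ratio in the knockout than in the wild type for 28 genes and a lower one for 5, of 12474 tested. Tagln, the smooth muscle actin-binding transgelin, showed a difference of −2.80 ± 0.42 (SE, 11 libraries, adjusted p = 0.0334). It stood at 174 ± 30.5 in total and 623 ± 170 in polysomal RNA of the wild type (SD, n = 3 each), and at 290 ± 118 (n = 2) and 143 ± 33.6 (n = 3) in the knockout. Ctgf, a matrix growth factor that responds to the cytoskeleton, differed by −1.57 ± 0.26 (adjusted p = 0.0344), the BMP antagonist Grem1 by −2.15 ± 0.37 (adjusted p = 0.0452), the replication clamp loader gene Dscc1 by −2.29 and Sprr2h by −3.46. Positive differences included the acetylcholine receptor subunit Chrnd at 2.51 ± 0.41 (adjusted p = 0.034), the calcium store protein gene Casq2 at 2.43, the lipid droplet gene Plin4 at 2.53 ± 0.33 (adjusted p = 0.0249) and the protease gene Adam8 at 2.47 ± 0.30. Ppp2r2b, Inadl, Krt19, Nefl, Ston2 and Myo7b, the other genes that the naming rule kept, had differences from 2.27 to 2.69. Myh3 had a difference of 3.47 ± 0.59 (adjusted p = 0.0413) while its mean was lower in polysomal RNA of both genotypes, at 2.18 in total and 0.0716 in polysomal RNA of the knockout, and neither edgeR (adjusted p = 0.361) nor DESeq2 (adjusted p = 0.147) called it. By edgeR, Casq2, Nefl and Myo7b did not pass either (adjusted p = 0.0519, 0.0662 and 0.0998). Of the 28, 13 had knockout means under 5 in both fractions, and 19 were also called by edgeR, as were all 5 of the others.

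Contractile genes were the list with most called members, 3 of 47 higher and 0 lower, 22 and 2 when adjusted over the list alone (median 1.21, camera adjusted p = 5.4e-09, adjusted p = 0.294 with an estimated correlation). Many of these genes were low in the knockout, where 35 passed the filter against 49 in the wild type. Adding 1 makes fold changes of low genes smaller, which can raise this median. Lists with lower medians in the knockout were cytosolic ribosomal proteins at −1.22 (camera adjusted p = 3.27e-14), mitochondrial ribosomal proteins at −0.92 (2.71e-15) and nuclear-encoded oxidative phosphorylation at −1 (2.36e-12), each with adjusted p = 0.294 with an estimated correlation. By limma 0 of their 74, 74 and 75 members were called, also when adjusted over the list alone, and after removal of the length trend the medians were −0.68, −0.47 and −0.46. Without knockout total replicate 2 they were −0.77, −0.61 and −0.55, and without wild-type polysomal replicate 2 that of the cytosolic ribosomal proteins was −0.81. Ribosome biogenesis factors had a median of −0.53, 0 of 92 called by limma and 24 lower when adjusted over the list alone (camera adjusted p = 7.56e-13, adjusted p = 0.289 with an estimated correlation). Ebna1bp2 stood at −1.97 (adjusted p = 0.0608) and Nop16 at −1.92 (adjusted p = 0.069). Small nucleolar RNA host genes had a median of −1.55 (camera adjusted p = 1.69e-06), G1/S replication genes −0.38 (0.000791), small nucleolar RNAs −0.60 (0.0222), mitochondrially encoded mRNAs 0.75 (0.0331) and the extracellular matrix 0.53 (0.0021), all with adjusted p = 0.294 with an estimated correlation. The actin and serum response list stood at −0.15 (camera adjusted p = 0.0454, adjusted p = 0.294 with an estimated correlation), translation factors at −0.46 and myoblast identity at 0.65 (camera adjusted p = 7.25e-05 and 0.0021, each with adjusted p = 0.289 with an estimated correlation), and fibroblast markers at 1.08 (camera adjusted p = 0.00113, adjusted p = 0.233 with an estimated correlation). Among these 9 lists limma called 1 matrix gene, Ctgf, 1 gene of the actin list, Tagln, and 0 in the others. Host gene medians were 1.28, 0 and −0.72 in knockout polysomal replicates 1 to 3 and overlapped those of the wild type (1.65, 2.56 and 1.02). The libraries' medians also overlapped between genotypes for cytosolic ribosomal proteins, ribosome biogenesis and oxidative phosphorylation. After removal of the length trend the small nucleolar RNAs turned to 0.89 and did not pass (camera adjusted p = 0.082), the matrix list stood at 0.22 and did not pass (camera adjusted p = 0.394), and the mitochondrially encoded mRNAs stood at 1.63 and translation factors at −0.29. Adjusted over the list alone, 7 matrix genes were higher and 2 lower, 7 and 2 of myoblast identity, all 5 fibroblast markers higher, 1 G1/S gene higher, 1 host gene lower, and 2 genes each of the actin list and the translation factors lower.

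The count of 28 and 5 genes came from 2604 at an unadjusted p under 0.05, and edgeR called 22 and 9 and DESeq2 489 and 462. By limma it fell to 0 and 0 without any 1 of wild-type total replicates 1 to 3, wild-type polysomal replicate 3 or knockout polysomal replicates 2 and 3. It was 25 and 3 without wild-type polysomal replicate 1, and became 218 and 137 without wild-type polysomal replicate 2 and 65 and 21 without knockout polysomal replicate 1.

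**Figure D4:**
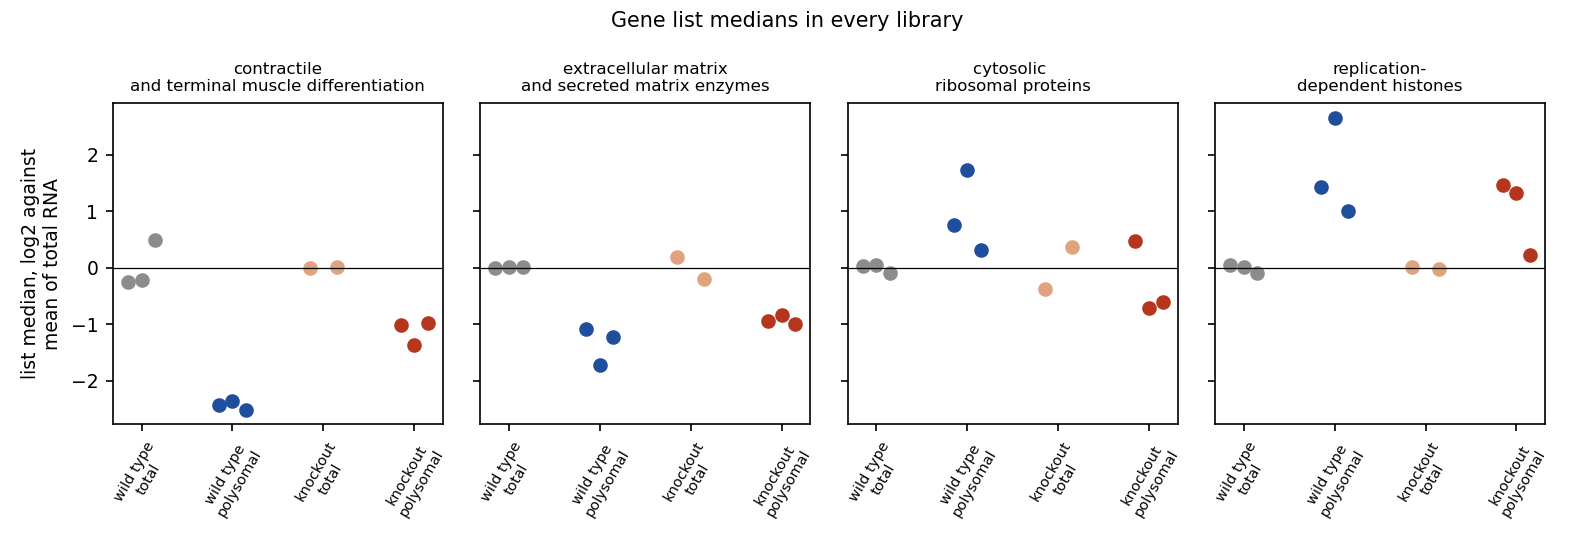
Median log2 level of 4 gene lists against the mean of the genotype's total RNA (y axis) in each library (x axis). Cytosolic ribosomal proteins stand at 0.75, 1.73 and 0.31 in wild-type polysomal replicates 1 to 3, at 0.48, −0.71 and −0.61 in the knockout ones, and at −0.37 and 0.37 in the 2 knockout total libraries.

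Total RNA of the knockout was compared with that of the wild type on 1 common scale, since the deposited tables were normalised separately. Genes listed for only 1 genotype were not tested, so they could not be called or named among the largest changes. Myod1 (ENSMUSG00000009471; GRCm38 chromosome 7, 46376474 to 46379092) fell by 6.38 ± 0.26 on the log2 scale (SE; 2 knockout and 3 wild-type libraries, adjusted p = 2.47e-07). Its deposited values were 137, 137 and 177 in the wild-type total replicates and 0.363 and 1.13 in the knockout ones. Reads of Myod1 numbered 39 in the 2 knockout total libraries and 10104 in the 3 wild-type ones, 194-fold lower on the common scale (95% exact Poisson interval of the knockout reads 142 to 273). Akap12, a kinase anchor gene, fell by 6.82 ± 0.34 (adjusted p = 5.64e-07), and the neurofilament genes Nefl and Nefm stood at −6.8 and −5.19. The signalling ligand Wnt7b stood at −5.45, the hyaluronan synthase Has1 at −4.9, the keratin Krt19 at −4.65, and Osbp2, Ccbe1 and Ptgis at −6.15, −5.12 and −5.01. The largest rises were Cck by 6.03 ± 0.42 (adjusted p = 8.56e-06), from 1.88 ± 0.414 (SD, n = 3) to 180 ± 73.3 (n = 2), Sprr2h by 4.39, the phagocyte oxidase subunit Ncf4 by 4.35, the surface glycoprotein gene Cd24a by 4.04 ± 0.27 and Wnt4 by 3.33.

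The extracellular matrix, contractile and myoblast identity lists were lower in knockout total RNA. In the extracellular matrix list 21 of 47 were lower and 0 higher, 22 and 4 when adjusted over the list alone (median −0.72, camera adjusted p = 7.9e-08, adjusted p = 0.418 with an estimated correlation). After removal of the length trend its median was −0.36, with 16 lower and 2 higher. Tenascin C (Tnc) fell by 3.92 ± 0.24 (adjusted p = 3.52e-06), from 967 ± 93.9 (n = 3) to 57.8 ± 10.1 (n = 2), and Loxl2, Lama2 and Mmp2 stood at −4.23, −3.8 and −3.58. Contractile genes had 17 of 47 lower and 1 higher, 21 and 1 when adjusted over the list alone (median −0.71, camera adjusted p = 7.9e-08, adjusted p = 0.478 with an estimated correlation). Xirp1 stood at −3.92, Myh3 at −3.49, the cardiac actin Actc1 at −3.19 and Jph2 at −2.13. The wild-type total replicates 1 to 3 themselves differed on the contractile list, with medians of −0.25, −0.22 and 0.5 against their mean. Myoblast identity genes had 10 of 29 lower and 3 higher, 14 and 5 when adjusted over the list alone (median −0.60, camera adjusted p = 0.000691, adjusted p = 0.357 with an estimated correlation). Notch1 stood at −2.24 and Des at −1.72 ± 0.25. Myog fell by 1.95 ± 0.45 (adjusted p = 0.0202), and Myf5, the early myogenic factor, rose by 0.99 ± 0.26 (adjusted p = 0.0355).

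Cell cycle lists were lower in knockout total RNA. G1/S replication genes had 6 of 43 lower and 0 higher, as many when adjusted over the list alone (median −0.23, camera adjusted p = 0.0194, adjusted p = 0.478 with an estimated correlation). E2f2 stood at −1.69, Uhrf1 at −1.31 and the cyclin Ccnd1 at −1.23. G2/M genes had 2 of 40 lower, Hjurp at −0.94 and Kif2c at −1, as many when adjusted over the list alone (median −0.50, camera adjusted p = 9.76e-05, adjusted p = 0.478 with an estimated correlation). Lists of short genes were higher. By limma oxidative phosphorylation had 7 of 75 higher and 0 when adjusted over the list alone (median 0.92, camera adjusted p = 3.89e-11), and cytosolic ribosomal proteins 4 of 74 and 0 (median 0.92, 9.41e-09). Mitochondrial ribosomal proteins had 4 of 73 and 1 (median 0.69, 1.29e-08), led by Mrpl13 at 2.60 ± 0.35, and small nucleolar RNA host genes 1 of 13 and 2 (median 1.11, 0.00102). All 4 had adjusted p = 0.478 with an estimated correlation, and the medians were 0.48, 0.42, 0.28 and 0.65 after removal of the length trend. Knockout total replicates 1 and 2 stood apart on these lists. Against their mean they were at −0.43 and 0.43 for oxidative phosphorylation and at −0.37 and 0.37 for cytosolic ribosomal proteins. Histones had 5 of 40 higher, as many when adjusted over the list alone, with Hist1h1c at 2.29 (median 0.15, camera adjusted p = 0.0418, adjusted p = 0.664 with an estimated correlation, and after removal of the length trend a median of −0.54 and camera adjusted p = 0.848). Among p53 targets 4 of 25 were higher and 2 lower, Pmaip1 at −3.13 and Plk2 at −1.68, and the list did not differ from other genes (median 0.16, camera adjusted p = 0.294). Of leukocyte markers, too few for a set test, 1 of 3 was higher, Csf1r at 1.57 (0.829 ± 0.206, n = 3, to 4.18 ± 1.25, n = 2), and all 3 when adjusted over the list alone (median 0.89). Of single genes from other lists, the stress response gene Atf3 fell by 2.34, Jun fell by 1.08, and the long non-coding RNA Pvt1 rose by 1.96.

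In total RNA 591 genes were higher and 715 lower of 12459 tested, 416 and 524 by at least 1 on the log2 scale. The higher genes had a median length of 2415 bases and the lower ones 5046, against 3573 for all. Without wild-type total replicate 1, 2 or 3 the counts were 195, 195 or 163 higher and 362, 351 or 305 lower. Without wild-type polysomal replicate 2, which enters through the shared spread, they were 1491 and 1499. DESeq2 called 1256 higher and 1208 lower.

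In polysomal RNA, on the same common scale of the separately normalised tables, Myod1 fell by 6.26 ± 0.23 on the log2 scale (SE, 3 libraries against 3, adjusted p = 1.53e-07). Its deposited values were 69.7, 95.5 and 79.3 in the wild type and 0, 0 and 0.0861 in the knockout, which is 2 reads over 3 libraries against 4725, 1910-fold lower (95% exact Poisson interval of the knockout reads 529 to 15800). Osbp2, Akap12, Ccbe1, Nefl, Rgs16, Ptgis, Has1 and Gap43 stood between −4.89 and −3.74. Ncf4 rose by 4.37 ± 0.38 (adjusted p = 5.5e-05), Cd24a by 3.6 ± 0.24, the transcription factor Maf by 3.30, Cck by 3.09, and the small proteoglycan gene Ogn by 3.01 ± 0.36 (adjusted p = 0.000456), from 66.7 ± 34.2 to 487 ± 207 (SD, n = 3 each).

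The ribosome biogenesis and G1/S replication lists were lower in knockout polysomal RNA, and mitochondrially encoded mRNAs were higher. Ribosome biogenesis factors had 17 of 92 lower and 0 higher, 34 and 0 when adjusted over the list alone (median −0.51, camera adjusted p = 4.54e-15, adjusted p = 0.133 with an estimated correlation). The rRNA methyltransferase gene Nop2 fell by 1.05 ± 0.19 (adjusted p = 0.00661), from 222 ± 31.6 to 99.9 ± 17.4 (SD, n = 3 each), Noc4l by 0.95, Noc2l by 0.81 and Tbl3 by 0.81. G1/S replication genes had 13 of 43 lower and 0 higher, 27 and 0 when adjusted over the list alone (median −0.61, camera adjusted p = 8.74e-14, adjusted p = 0.133 with an estimated correlation). The helicase subunit genes Mcm2 and Mcm5 stood at −0.99 and −0.85 and the polymerase gene Pold1 at −1.10. Of mitochondrially encoded mRNAs, 6 of 7 were higher, 7 when adjusted over the list alone (median 1.48, camera adjusted p = 1.81e-05, adjusted p = 0.133 with an estimated correlation). The respiratory chain genes mt-Nd5, mt-Nd2, mt-Nd4 and mt-Co1 rose by 1.56, 1.51, 1.48 and 1.43. Knockout polysomal replicates 1 and 2, with 23.136% and 32.663% of rRNA-like reads, had medians of this list of −0.07 and 0.47 against knockout total RNA, and replicate 3, with 0.385%, had 0.86.

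The extracellular matrix had 17 of 47 lower and 4 higher, 20 and 8 when adjusted over the list alone (median −0.34, camera adjusted p = 7.55e-05, adjusted p = 0.20 with an estimated correlation). Mmp2 stood at −3.18, Loxl2 at −3.03, Tnc at −2.69 and Fbln2 at −1.60. In the actin and serum response list 4 of 35 were lower and 0 higher, as many when adjusted over the list alone (median −0.42, camera adjusted p = 2e-05, adjusted p = 0.133 with an estimated correlation). These were Tagln at −2.01, Tagln2 at −1.40, Myh10 at −1.34 and Egr1 at −1.21. Among p53 targets 5 of 25 were higher and 2 lower, 10 and 3 when adjusted over the list alone (median 0.38, camera adjusted p = 0.0285, adjusted p = 0.172 with an estimated correlation). Sulf2 stood at 2.33, Trp53inp1 at 2.19 and Pmaip1 at −2.14. Fibroblast markers had 2 of 5 higher, Ly6a at 1.07 and Mfap5 at 0.91, and 3 when adjusted over the list alone (median 0.91, camera adjusted p = 0.00867, adjusted p = 0.133 with an estimated correlation). The adipocyte markers Plin4 and Cebpa rose by 2.17 and 1.80, and 1 of 3 leukocyte markers, Csf1r, by 1.29. The stress response list had 4 of 35 lower, Slc7a5 at −0.93, Shmt2 at −0.89, Asns at −0.81 and Mthfd2 at −0.73, and 5 when adjusted over the list alone (median −0.09, which turned positive under quantile normalization, camera adjusted p = 0.0439, adjusted p = 0.138 with an estimated correlation). It did not pass after removal of the length trend (camera adjusted p = 0.0611).

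Few members passed in other lists that differed from other genes. Translation factors had 1 of 47 lower (median −0.29, camera adjusted p = 0.000908, adjusted p = 0.172 with an estimated correlation). G2/M genes had 1 of 40 lower, Cdk1 at −0.83 (median −0.25, camera adjusted p = 0.000416, adjusted p = 0.356 with an estimated correlation). Mitochondrial ribosomal proteins had 1 of 73 lower, Mrpl35 at −0.92, and histones 1 of 40 higher, Hist2h3c2 at 1.92 (medians −0.25, or −0.14 after removal of the length trend, and 0.59, camera adjusted p = 0.000522 and 0.000908, each with adjusted p = 0.68 with an estimated correlation). By limma 0 of 74 cytosolic ribosomal proteins, 0 of 13 small nucleolar RNA host genes and 0 of 18 interferon genes passed (medians −0.30, −0.65 and 0.35, camera adjusted p = 0.0111, 0.0285 and 0.0387, with adjusted p = 0.797, 0.68 and 0.138 with an estimated correlation). Contractile genes had 5 of 47 higher, among them the acetylcholine receptor subunit Chrng at 1.83, and 4 lower, Jph2 at −2.24 among them, and did not differ from other genes (camera adjusted p = 0.665). Myoblast identity genes had 1 of 29 higher, Rapsn at 1.24, and 4 lower (median 0.21, mean −0.07, camera adjusted p = 0.941).

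In polysomal RNA 639 genes were higher and 415 lower of 12459 tested, 442 and 192 by at least 1 on the log2 scale. Without wild-type polysomal replicate 2 the limma count was 954 and 710, without wild-type polysomal replicate 3 it was 395 and 260, without knockout polysomal replicate 2 or 3 it was 389 and 240 or 277 and 154. Wild-type total replicates 1 and 2 enter through the shared spread, with 250 and 239 genes lower without them and 422 higher without the latter. DESeq2 called 973 and 822, and removing the length trend gave 641 lower.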

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

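The comparison with matched random lists and the run with single libraries left out were chosen before their own outcome, but after the length-corrected medians and the gene counts with libraries left out had been seen. The split of libraries into other groups was chosen after the results were seen.

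The lower medians of cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation and mitochondrial ribosomal proteins in the difference of polysomal enrichment, at −1.22, −1 and −0.92, may have 3 sources. The first is the length trend between libraries: random lists matched on length and expression had medians of −0.44, −0.64 and −0.42. Each real list lay at percentile 0.01, the smallest that 10000 lists can give. The random lists could hold genes of the real lists and drew genes 1 by 1, although genes of a list move together. Removal of the length trend left medians of −0.68, −0.46 and −0.47. Length thus accounts for part of the difference, and whether it accounts for all is not settled. The second is 1 library alone: the median closest to 0 was −0.55, for oxidative phosphorylation without knockout total replicate 2, so no single library carries the sign. The last source is a hypothesis: knockout polysomes could hold less of these short mRNAs. With an estimated correlation between genes none of the 3 lists passed (adjusted p = 0.294 for each), so a difference of these lists is not established.

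Other differences between the genotypes are given as values. The polysomal over total ratio was higher in the knockout for 28 genes and lower for 5. Of 100 splits of the 11 libraries, the real one among them, 5 called at least as many, the highest other split calling 3054. These splits regrouped total and polysomal libraries separately, so some of them hold the difference between the genotypes itself. They cannot say how often chance gives such a count, and chance is not excluded for it. Among the 28, the genes that the naming rule kept were Adam8 at 2.47, Casq2 at 2.43, Chrnd at 2.51, Inadl at 2.55, Krt19 at 2.29, Myh3 at 3.47, Myo7b at 2.27, Nefl at 2.29, Plin4 at 2.53, Ppp2r2b at 2.69 and Ston2 at 2.28. The 5 were Ctgf at −1.57, Dscc1 at −2.29, Grem1 at −2.15, Sprr2h at −3.46 and Tagln at −2.8. Further list medians were −0.46 for translation factors, −0.53 for ribosome biogenesis factors, 0.75 for mitochondrially encoded mRNAs, −1.55 for small nucleolar RNA host genes and −0.6 for small nucleolar RNAs, which became 0.89 after removal of the length trend. They were 0.65 for myoblast identity, 1.21 for contractile genes, −0.38 for G1/S replication, 0.53 for the extracellular matrix, −0.15 for the actin and serum response and 1.08 for fibroblast markers.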

How the results depend on the processing

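Length correction and the run without the 3 rRNA-rich polysomal libraries were chosen after the data were seen, the other settings before. That run leaves 1 knockout polysomal library, replicate 3, so its counts for the knockout, the difference and polysomal RNA rest on a group of 1 with the spread taken from the other groups. Counts with a knockout total library left out are not given for comparisons with knockout total RNA, since 1 library would remain in that group. No paired analysis was possible for polysomal against total RNA in the knockout or for knockout against wild type in total or polysomal RNA, because the numbers of the knockout columns cannot be tied to numbered samples, and a block on the column numbers themselves was not run. In the difference between genotypes only the wild-type numbers could be blocked. Where values moved, the cause was not tested. Directions held nearly everywhere: of the named genes, 2 results reversed, Myod1 in the difference between genotypes with DESeq2 (−3.37, adjusted p = 0.0453) and Rps27 in total RNA after length correction (−0.06, adjusted p = 0.937). A further 56 results changed sign where neither the main fit nor the other setting called the gene. Pseudocount 0.25, no filter, median scaling and no variance trend moved no count of called genes by over 1.5 times.

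In wild-type polysomal against total RNA, 1101 genes were higher and 1705 lower. DESeq2 called 2154 higher, the authors' deposited FDR 1735 higher, a limit of 1 on the log2 scale 560 higher and 1125 lower, and the run without the rRNA-rich libraries 2765 and 3012. With 1 library left out the counts ran from 83 to 2765 higher and from 378 to 3012 lower. They were 114 and 420, 144 and 437, and 83 and 378 without total replicates 1 to 3, 594 higher without polysomal replicate 1, and 2765 and 3012 without polysomal replicate 2. The wild-type samples share only a replicate number between fractions, and with it as a block limma called 703 higher and 1243 lower. Same-number correlations of the libraries' deviations were 0.21, −0.22 and −0.07 and different-number ones −0.31 to 0.26, and not every sample correlated best with its own number. The set test passed 12 lists, 0 by camera with an estimated correlation and 19 by fry in either direction. Those 19 include the G2/M and stress response lists, which did not differ from other genes by camera.

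In the knockout, 110 genes were higher and 223 lower. DESeq2 called 537 and 751, the authors' deposited FDR 446 and 630, a fit of all 11 libraries 420 and 542, and the length correction 609 and 855. With 1 polysomal library left out the counts ran from 16 to 862 higher and from 20 to 760 lower. They were 862 and 760, 35 and 147, and 16 and 20 without polysomal replicates 1 to 3. The set test passed 8 lists, 0 by camera with an estimated correlation and 3 by fry in 1 direction.

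For the difference between the genotypes, 28 genes were higher and 5 lower. Pseudocount 4 gave 56 and 10, a mean of at least 5 gave 16 and 3, quantile normalization 13 and 1, edgeR 22 and 9, DESeq2 489 and 462, the length correction 123 and 52, and the run without the rRNA-rich libraries 642 and 467. With the wild-type replicate number as a block limma called 0 and 0, against 2604 genes at an unadjusted p under 0.05. With 1 library left out limma called from 0 to 218 higher and from 0 to 137 lower. These were 0 and 0 without each wild-type total replicate, wild-type polysomal replicate 3 and knockout polysomal replicates 2 and 3. They were 25 and 3 without wild-type polysomal replicate 1, 218 and 137 without wild-type polysomal replicate 2, and 65 and 21 without knockout polysomal replicate 1. The set test passed 14 lists, 0 by camera with an estimated correlation, 2 by fry in 1 direction and 7 by fry in either.

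Between the genotypes in total RNA, 591 genes were higher and 715 lower, with DESeq2 1256 and 1208, and without the rRNA-rich libraries 2354 and 2312. With 1 library other than a knockout total one left out, the counts ran from 163 to 1491 higher and from 305 to 1499 lower. They were 195 and 362, 195 and 351, and 163 and 305 without wild-type total replicates 1 to 3, 1491 and 1499 without wild-type polysomal replicate 2, and 81 and 181 without knockout total replicate 2. The set test passed 10 lists, 0 by camera with an estimated correlation and 3 by fry in 1 direction.

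In polysomal RNA, 639 genes were higher and 415 lower, with DESeq2 973 and 822, 641 lower after the length correction and 708 lower without the rRNA-rich libraries. With 1 library left out the counts ran from 277 to 954 higher and from 154 to 710 lower. They were 250 lower without wild-type total replicate 1, 422 and 239 without replicate 2, 710 lower without wild-type polysomal replicate 2, 395 and 260 without replicate 3, 389 and 240 without knockout polysomal replicate 2, and 277 and 154 without replicate 3. The set test passed 15 lists and 0 by camera with an estimated correlation.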

Other observations

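Among the tests described here, the rRNA carry-over test was chosen before its outcome was known and all others after the results were seen. A small set of genes was close to off in the knockout. Only genes listed for both genotypes could be counted, which leaves out 741 listed only for the wild type and 437 only for the knockout. Genes without a read in 1 genotype may be among those left out. Of 7605 shared genes with a wild-type total mean of at least 20 on the common scale, 11 had a knockout total mean under 1: Akap12, Ccbe1, Gap43, Has1, Krt19, Lama2, Loxl2, Myod1, Osbp2, Sorbs2 and Wnt7b, all under 2 in knockout polysomal RNA too. In total RNA Sprr2h was the only shared gene the other way round, of 7539 with a knockout total mean of at least 20, and its wild-type polysomal mean was 5.54. A list of 47 immediate-early and other short-lived mRNAs was put together after Fos, Fosb and Atf3 had been seen, and 19 of the 47 are also in 5 of the fixed lists. It had 29 genes higher and 1 lower in wild-type polysomal RNA, 30 and 1 when adjusted over the list alone, and 12 and 0 in the knockout, 24 and 2 when adjusted over the list alone. Its genes were chosen for this pattern, so these counts describe the list and test nothing.

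Of the possible explanations for contractile genes low and Fos and Fosb high in polysomal RNA of both genotypes, 3 were looked at. A true difference in how these mRNAs are held in polysomes, which the series was made to measure, was not tested apart from them. Removal of the length trend left the contractile median at −2.21 in the wild type and −1.12 in the knockout, so length is not the cause for these genes. Leaving out the rRNA-rich libraries left the wild-type median at −2.48, with Fos at 4.02 and Fosb at 3.32. The contractile medians of wild-type polysomal replicates 1 to 3 were −2.43, −2.36 and −2.51, at rRNA-like shares of 5.915%, 14.547% and 0.674%. These values argue against rRNA carry-over as the cause for the contractile list there. For Fos and Fosb it is not excluded, since replicate 1 stayed in that run and carry-over was reduced but not removed. The knockout value of −0.99 rests on polysomal replicate 3 alone. The cells behind the 2 kinds of RNA may also have been in different states, a hypothesis that cannot be tested here. If both came from 1 pool, the Fos folds of 26.7 and 32.2 allow at most 3.7% and 3.1% of mRNA in polysomes on average, a share that was not measured.

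Myod1 near 0 in the knockout might have several explanations. Libraries of a cell type outside the muscle lineage are excluded, since Des, Cdh15 and Myf5 were all at least 71.4 in every knockout library. A deletion that took the expressed neighbours as low as Myod1 is excluded as well. The 6 nearest tested genes had medians of 0 in total and −0.41 in polysomal RNA, the lowest value being −0.58 for Ccdc114 in polysomal RNA. None passed, but simulated 2-fold changes were recovered for only 18% of genes in total and 16% in polysomal RNA. A smaller loss of these neighbours is therefore not excluded. A loss of Myod1 alone, a difference between clones and an effect of the Ddx27 knockout remain as untested hypotheses.

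Neighbouring genes shifted together between the genotypes. The largest median over 41 neighbouring genes was 0.63 in size in total RNA, against a highest of 0.63 in 1000 shuffled orders, so it passes narrowly, with a permutation p = 0.001, the smallest possible. This window, on chromosome 6, stood at −0.63 in total and only −0.23 in polysomal RNA, where the largest window of all was 0.51 in size, against a highest of 0.47 in the shuffled orders. The chromosome test was chosen after these medians were seen. Genes of chromosome 6 had medians of −0.23 in total and −0.24 in polysomal RNA, those of chromosome 13 had 0.17 and 0.14, and these 2 lay beyond all 1000 shuffles in both. Chromosomes 8 (0.18 and 0.06) and 12 (−0.19 and −0.04) lay beyond them in total RNA only. In polysomal RNA only, chromosomes 5 (−0.11 and −0.11) and 14 (0.02 and 0.11) did. Copy-number differences between the lines could give such shifts, the smaller polysomal value of the window leaves this open, and no DNA was examined here.

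Regrouping the libraries was tried after the results were seen. In wild-type polysomal against total RNA, 1 of 10 splits, the real one, called 2806 genes and the highest other 0. In the knockout 1 of 10 did, with 333 against 9. Between genotypes 1 of 10 did in total RNA, with 1306 against 0, and 1 of 10 in polysomal RNA, with 1054 against 15. With 10 splits no share under 0.05 is possible.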
